A study of Mus musculus with 22 samples.

How the data were processed

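RNA-seq libraries of mouse bladder organoids, epithelial cultures grown in 3 dimensions, were compared between Arid1a wild type (WT) and Arid1a knockout (KO). Arid1a encodes a DNA-binding subunit of the BAF (SWI/SNF) chromatin remodelling complex. Of the 22 libraries, 18 came from primary bladder urothelial organoids: total RNA, the subpolysome fraction and the polysome fraction of a sucrose gradient, each from 3 WT and 3 KO samples. The other 4 were total RNA libraries of bladder cancer organoids, 2 labelled WT and 2 labelled KO. The polysome fraction holds mRNAs carrying several ribosomes, and the subpolysome fraction holds those carrying few or none. Groups and replicate numbers were taken from the labels.

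The deposited values were raw read counts per gene symbol for 24421 genes, whole numbers with no normalization. Per the labels' protocols, RNA was purified on silica columns with DNase treatment and libraries followed standard Illumina preparation. Per the submitters' processing notes, reads were counted with HTSeq against the mm10 mouse genome, and Bowtie was named as well for the 18 organoid libraries outside the cancer set. No aligner was named in those notes for the 4 cancer libraries. Tool versions, the annotation used for counting, the treatment of strand and of reads matching several places, and the part of Arid1a that was deleted are not given in the sources used here. Bowtie does not place reads across exon junctions by itself, and whether a spliced aligner was run is not given either. Without strand, reads of a gene and of an overlapping antisense gene fall together, and genes with near-identical copies, such as ribosomal protein genes and their pseudogenes, may exchange reads. Counts are relative to each library's total, so the amount of RNA in a gradient fraction was not measured by them.

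Total counts per library ranged from 66227600 to 74605489 for organoid total RNA, from 64911189 to 76594655 for polysomes, from 39245248 to 51628570 for subpolysomes and from 48429672 to 55431426 for cancer organoids. Levels are given in CPM, counts scaled to a common library size, and a gene at 1 CPM rested on at least 39.2 counts. Libraries of the same group were compared in pairs by a chi-square statistic of their counts over genes. It lay between 11.9 and 247 times its degrees of freedom, so no library was a second copy of another of its group, and pairs from different groups were not compared in this way. Nothing in the labels says that replicates came from separate animals or separately derived cultures, so p-values measure the spread between these libraries, which may be technical. The share of counts on Rn45s, the ribosomal RNA precursor, ran from 0.191% to 5.59%.

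Each comparison was fitted with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr, glmQLFit and the quasi-likelihood F test, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. WT and KO were compared within total RNA, within polysomes and within subpolysomes, each on its own 6 libraries. Polysome association was tested as the interaction of genotype and fraction over the 12 polysome and subpolysome libraries, and over the 12 polysome and total RNA libraries. The first of these fits also gave polysome against subpolysome within each genotype. The 4 cancer libraries were fitted alone, and the difference between both KO effects was an interaction over 10 total RNA libraries. Standard errors of log2 fold changes were taken as the log2 fold change over the square root of F. Means with SD are CPM scaled by TMM factors unless said otherwise, and values given for single libraries are CPM of the library's own total. A count of genes whose groups of libraries do not overlap is set beside the share expected by chance.

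A total of 39 gene lists (pathways, complexes and markers of cell types that a bladder culture can hold) were written from general knowledge and tested with camera of limma 3.58.1 on the same fits, with a preset correlation of 0.01 and at least 5 tested members. Adjustment was over the lists of a comparison. The test was run again with an estimated correlation between genes. That run used log2 CPM in place of the fitted counts, so the runs differ in input as well as in the correlation. Named genes followed a rule. In total RNA, in the polysome to subpolysome ratio and in the cancer libraries these were the 8 highest and 8 lowest called genes with average log2 CPM of at least 4 and no overlap between groups, leaving out predicted models and pseudogenes, and the 3 members with the smallest p of each list past its threshold. In the other comparisons they were the 5 highest and 5 lowest. A fixed set was added in every comparison: Arid1a, Arid1b, Eef2k, Eef2, Myc, Ccnd1, Mki67, Cdkn1a, Atf4, Krt5, Upk2, Trp63, Pparg, Cdkn2a, Slc7a11, Anxa1 and Pik3ip1. Groups, tests, lists, this rule and the alternatives were fixed before the data were examined, except where a later choice is named as such. Not every gene the rule allows is described, and some are not reported here.

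Alternatives were size factors of the DESeq2 kind, library size only, no filter on low counts, the Wald test of DESeq2 1.42.0, a replicate block, a fit on all 18 organoid libraries, and each library or culture left out in turn. Alternatives added after seeing the data left out 4 genes that carry ribosomal RNA reads (Rn45s, Mir6236, Mir6240 and Lars2), crossed the pairing of the cancer libraries, or kept genes of average log2 CPM of at least 1. Whether replicate numbers pair the libraries was checked by correlating the deviations of same-numbered WT and KO libraries from their group means. In the polysome fraction the correlations were 0.186, 0.197 and 0.249, all above every other pairing, and the numbers, which come from the sample titles, were taken to pair those libraries. The blocked polysome fit called 5030 genes, 3756 of them among the 3757 called without the block.

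The fits were tested on simulated counts drawn from the real means and library sizes, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. In the total RNA comparison 85.1%, 88.1% and 97.0% of these were called. For the polysome comparison the shares at 1.5-fold and 2-fold were 47.8% and 88.1%, and for the subpolysome comparison 49.3% and 74.6%. In the polysome to subpolysome interaction 11.9%, 44.8% and 78.8% were called, and in the polysome to total interaction 31.3%, 76.1% and 93.9%. In the cancer comparison 0%, 0% and 16.7% were called, and in the interaction with the cancer libraries 0%, 2.99% and 40.9%. Of the calls 21.4% (3 of 14) were false in the cancer comparison and 8.79% (21 of 239) in total RNA, and in the others the share ran from 2.21% (polysomes) to 6.88% (polysome to total interaction). A further list of genes was raised 1.5-fold to try the list test, and calls of its members count as true in these shares.

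Gene positions are from RefSeq on GRCm38.p6, the assembly of mm10, in which 24313 of the 24421 symbols (99.6%) were matched by symbol or synonym. Coding lengths are the longest coding sequence per gene in the GENCODE basic annotation of the same assembly. Plots were drawn with matplotlib 3.10.9 under python 3.11.15. All 22 libraries and all gene entries in the files were used.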

Results

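RNA of primary mouse bladder urothelial organoids, WT and KO for Arid1a, was sequenced as total RNA and as the subpolysome and polysome fractions of a gradient (3 libraries per genotype and kind of RNA), beside total RNA of bladder cancer organoids (2 libraries labelled WT and 2 labelled KO). The 22 libraries held 39245248 to 76594655 counts each. The comparisons ask how loss of Arid1a goes with mRNA levels and with the loading of mRNAs on polysomes. Total RNA differed widely between the genotypes, and genes that passed both in total RNA and in a gradient fraction changed in the same direction, but for 5 in subpolysomes. In the polysome to subpolysome ratio, taken relative to other mRNAs, 1 gene passed, and 12 with the replicate block. The luminal, cell cycle and glutathione gene lists rose in the KO organoids, though the luminal genes Krt20, Krt7 and Cldn4 fell, and the lists of epithelial to mesenchymal transition and of NFkB cytokines fell. These list calls rest on a preset correlation between genes. With an estimated correlation 0 lists passed in every comparison, also where nearly all members of a list changed in 1 direction. What that run can find was not measured, so it does not tell the lists apart. In the bladder cancer organoids no gene passed the test, and the Arid1a counts of 2 of the 4 libraries ran against their labels.

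Arid1a reads were lower, but not absent, in the KO organoids. The gene lies on chromosome 4 (133679008 to 133756769, GRCm38) and had 139, 156 and 141 CPM in WT total RNA and 93.2, 93.8 and 106 CPM in KO total RNA, a fall of 1.51 times (log2 -0.60, SE 0.06, adjusted p = 5.68e-06; every KO library below every WT library). Reads from parts of the gene outside the deleted one would still be counted. In polysomes the values were 40.4, 27.6 and 22.9 CPM in WT and 28.7, 23 and 15.3 CPM in KO (log2 -0.48, SE 0.20, adjusted p = 0.0817). KO was lower than the same-numbered WT library in 3 of 3 pairs, and Arid1a passed with the replicate block (log2 -0.49, adjusted p = 0.00056) and when KO 1 (adjusted p = 0.0167) or WT 3 (0.0200) was left out. It passed as well with no filter (0.00758) and in the fit on all 18 libraries (0.0131), the range over alternatives being 0.00056 to 0.397. In subpolysomes Arid1a had 42.9, 39.9 and 33.7 CPM in WT and 47.8, 43.0 and 39.2 CPM in KO (log2 0.19, SE 0.12, adjusted p = 0.276). There KO was higher than the same-numbered WT library in 3 of 3 pairs, the opposite direction to polysomes. In the cancer organoids the libraries labelled WT had 79.2 and 227.5 CPM and the libraries labelled KO had 201.2 and 64.1 CPM. The library labelled WT 1 thus lay near the one labelled KO 2, and the library labelled KO 1 near the one labelled WT 2, so every cancer comparison below holds only as labelled. The library labelled KO 2 also had 12 counts of the Y-linked gene Ddx3y, against 3478, 2578 and 2896 in the other 3.

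**Figure D1:**
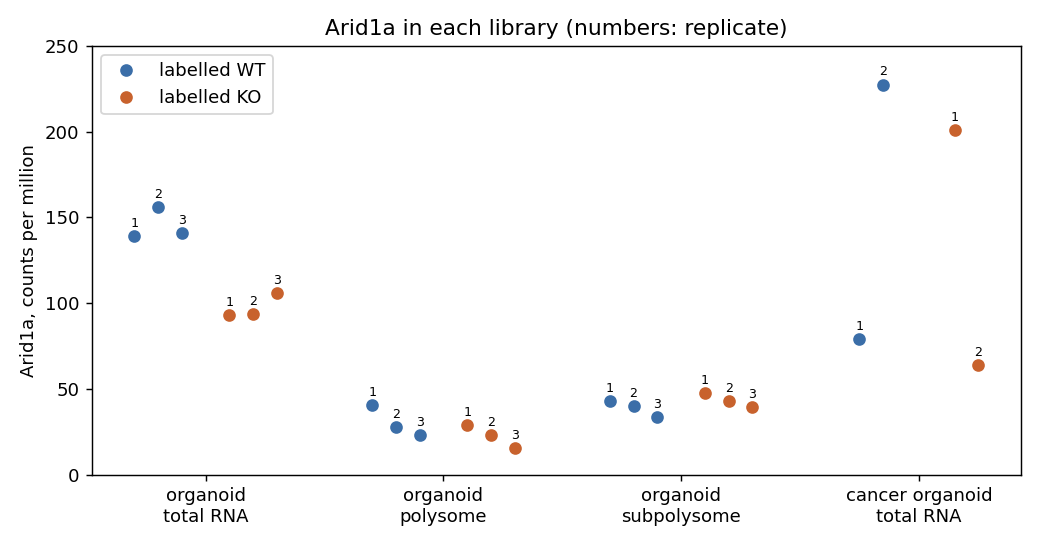
Arid1a CPM in each library, blue for libraries labelled WT and orange for those labelled KO. In organoid total RNA the 3 KO libraries (93.2 to 106 CPM) lay below the 3 WT libraries (139 to 156), while in the cancer organoids the library labelled WT 1 had 79.2 CPM and the one labelled KO 1 had 201.2.

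In organoid total RNA the imprinted long noncoding RNA H19 rose most among well expressed genes, from 36.2 ± 10.1 to 916 ± 107 CPM (mean ± SD, n = 3 and 3), a rise of 25.3 times. Upk3b (9.29 times) and Upk3a (5.12 times), uroplakins of the bladder surface, rose as well. The largest falls among genes with average log2 CPM of at least 4 were of Ctla2a, a cysteine protease inhibitor (53.1 times), Slco2a1, a prostaglandin transporter (51.3 times), and Adam12, a membrane metalloprotease (33.7 times). Of 13198 genes tested, 3557 were higher and 3468 lower in KO (53.2% in all), and 920 and 747 of these changed at least 2 times. Groups of libraries did not overlap for 61.1% of genes, against 10% by chance. Fitted together with the fractions on all 18 libraries, 3784 genes passed, 3717 of them among the 7025 above.

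Among the genes with the largest changes, H19 (log2 4.66, SE 0.17, adjusted p = 2.41e-09), Upk3b (log2 3.22, SE 0.10, 8.01e-10), Wif1, a secreted Wnt inhibitor (log2 2.92, SE 0.13, 1.02e-08), Fgfr3, a fibroblast growth factor receptor often mutated in bladder tumours (log2 2.82, SE 0.12, 6.67e-09), and Ndrg2 (log2 2.63, SE 0.06, 1.10e-10) had all 3 KO libraries above all 3 WT libraries. All 3 KO libraries lay below all 3 WT libraries for Ctla2a (log2 -5.73, SE 0.27, 1.66e-08, and -6.38 without KO 2), Slco2a1 (log2 -5.68, SE 0.12, 1.10e-10) and Adam12 (log2 -5.07, SE 0.21, 7.44e-09). The same held for Col4a1 and Col4a2, the paired chains of basement membrane collagen (log2 -3.40, SE 0.10, 8.05e-10, and log2 -3.37, SE 0.13, 3.50e-09), and for Csf2, the cytokine GM-CSF (log2 -3.36, SE 0.16, 1.73e-08). Chosen after their values were seen, Igf2, the imprinted growth factor next to H19, rose (log2 3.45, SE 0.09, adjusted p = 4.44e-10), from 2.04 ± 0.16 to 22.3 ± 0.45 CPM, and fibronectin, Fn1, fell (log2 -3.23, SE 0.19, 9.93e-08). Ctla2a, and below Oas1a, Gstm1 and Akr1c13, belong to families of similar genes that may share reads.

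Luminal genes rose as a group. Of 28 tested members 22 rose and 3 fell (median log2 0.66, adjusted p = 3.34e-14; adjusted p = 0.667 with an estimated correlation), with the same counts adjusted over the list alone. Upk3a (log2 2.36, SE 0.09, adjusted p = 5.13e-09) and Pparg, a nuclear receptor of luminal differentiation (log2 1.23, SE 0.06, adjusted p = 3.01e-08), rose in all 3 KO libraries. The members that fell were Krt7 and Cldn4, an epithelial keratin and a tight junction claudin, and Krt20, a keratin of the outermost umbrella cells. Krt20, named after its value was seen, went from 6.63 ± 0.27 to 1.55 ± 0.62 CPM (log2 -2.10, SE 0.23, adjusted p = 1.28e-05). Squamous differentiation genes rose as a list, 14 of 27 rising and 5 falling, with the same counts adjusted over the list alone (median log2 0.37, adjusted p = 0.000818; adjusted p = 0.808 with an estimated correlation). The cornified envelope genes Evpl (log2 1.49, SE 0.07) and Rptn (log2 1.92, SE 0.10) were higher in all 3 KO libraries, at adjusted p = 2.08e-08 and 4.70e-08. Krt1, Krt10, Sprr1b, Sprr2d and Sprr2h, which mark squamous cells as well, fell. Basal urothelial genes split, 11 of 30 rising and 13 falling, with a median of -0.04 and a mean of 0.03 (adjusted p = 0.559). Trp63, the transcription factor of basal cells, rose (log2 0.53, SE 0.05, adjusted p = 7.85e-06) in all 3 KO libraries.

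Cell cycle genes rose almost throughout. In the mitosis list 51 of 52 members rose and 1, Gtse1, a microtubule-bound protein of late cell cycle, fell, also when adjusted over the list alone (median log2 1.64, adjusted p = 2.98e-12; adjusted p = 0.714 with an estimated correlation). Cdk1, the kinase that starts mitosis, rose 2.69 times (log2 1.43, SE 0.14, adjusted p = 4.79e-06), beside Aurkb, a kinase of chromosome segregation (log2 1.75, SE 0.17, 5.26e-06), and the proliferation marker Mki67 (log2 1.67, SE 0.24, 0.000109), each in all 3 KO libraries. In the DNA replication list 56 of 60 rose and 0 fell, 57 and 0 when adjusted over the list alone (median log2 0.85, adjusted p = 8.51e-12; adjusted p = 0.714 with an estimated correlation). The replicative helicase subunits Mcm5 (log2 1.86, SE 0.15, 1.38e-06) and Mcm6 (log2 1.76, SE 0.15, 1.35e-06) rose in all 3 KO libraries. The p53 target list fell, 18 of 32 members falling and 5 (Sesn1, Fas, Plk3, Ddb2 and Ckap2) rising, the same when adjusted over the list alone (median log2 -0.18, adjusted p = 0.0248; adjusted p = 0.689 with an estimated correlation). Cdkn1a, a cell cycle inhibitor induced by p53, fell (log2 -0.59, SE 0.04, adjusted p = 3.99e-07) in all 3 KO libraries. Cdkn2a, a member of this list that acts upstream of p53, fell 2.59 times (log2 -1.37, SE 0.09, 1.69e-07), also in all 3.

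Genes of the epithelial to mesenchymal transition (EMT) fell, 16 of 19, and 1, the transcription factor Snai2, rose, with the same counts adjusted over the list alone (median log2 -1.28, adjusted p = 5.03e-11; adjusted p = 0.714 with an estimated correlation). They included the matrix protein Tgfbi, down 5.62 times (log2 -2.49, SE 0.06, adjusted p = 3.37e-10), the activin subunit Inhba, down 5.73 times (log2 -2.52, SE 0.12, 2.18e-08), and the matrix protein Tnc (log2 -1.83, SE 0.09, 1.60e-08), each lower in all 3 KO libraries. Targets of the Hippo pathway effector YAP fell in 11 of 18 cases, 12 when adjusted over the list alone, and Ajuba, a LIM protein that restrains Hippo signalling, rose (median log2 -0.27, adjusted p = 0.0141; adjusted p = 0.714 with an estimated correlation). Nt5e, an ecto-enzyme that makes adenosine (log2 -1.62, SE 0.10, 1.69e-07), and Cyr61, a secreted matrix protein (log2 -0.59, SE 0.07, 2.99e-05), were lower in all 3 KO libraries. Annexins, membrane-binding proteins, fell in 6 of 11 cases, 7 when adjusted over the list alone (median log2 -0.37, adjusted p = 0.0248; adjusted p = 0.714 with an estimated correlation), while Anxa3, Anxa9 and Anxa11 rose. Anxa6 (log2 -2.15, SE 0.07, 1.10e-09) and Anxa1 (log2 -0.47, SE 0.04, 2.41e-06) were lower in all 3 KO libraries. Fibroblast and matrix genes had a median log2 of -1.04 but a test direction upward (2 rose and 5 fell of 11, 3 and 5 adjusted over the list alone, adjusted p = 0.975).

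Interferon response genes rose in 21 of 40 cases and 5 fell, among them the transcription factor Irf1, the guanylate-binding proteins Gbp2 and Gbp3, and Parp14, the same when adjusted over the list alone (median log2 0.61, adjusted p = 0.00259; adjusted p = 0.667 with an estimated correlation). Oas1a, an antiviral synthetase (log2 2.08, SE 0.16, adjusted p = 7.55e-07), and Irf9, a subunit of the interferon-induced transcription factor (log2 0.73, SE 0.06, 9.23e-07), were higher in all 3 KO libraries. Cytokines of the NFkB pathway fell in 18 of 30 cases, the same when adjusted over the list alone (median log2 -0.30, adjusted p = 0.00358; adjusted p = 0.714 with an estimated correlation). The cytokine Lif was lower in all 3 KO libraries (log2 -1.69, SE 0.07, 3.79e-09). Of the 4 members that rose (Il33, Il18, Cxcl15 and Ccl20), Il33, a nuclear alarm cytokine of epithelia, was higher in all 3 (log2 0.96, SE 0.04, 1.18e-08). Markers of immune cells stayed few: 5 of the 25 listed were expressed enough to be tested, of which 2 rose and 0 fell (adjusted p = 0.559), and no hemoglobin gene was.

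Several metabolic groups rose. Of 37 glutathione and NRF2 genes, 27 rose and 4 (Gsr, Me1, Akr1b8 and Akr1c13) fell, 27 and 5 when adjusted over the list alone (median log2 0.38, adjusted p = 6.10e-09; adjusted p = 0.667 with an estimated correlation). The glutathione transferase Gstm1 rose 4.97 times (log2 2.31, SE 0.07, adjusted p = 1.26e-09) and the cystine transporter Slc7a11 3.75 times (log2 1.91, SE 0.09, 2.06e-08), while the reductase Akr1c13 fell (log2 -1.71, SE 0.08, 1.34e-08), each in all 3 KO libraries. Glycolysis and hypoxia genes rose in 25 of 35 cases and 1 fell, Ddit4, an inhibitor of mTOR signalling induced by stress, with 26 and 2 when adjusted over the list alone (median log2 0.48, adjusted p = 6.44e-07; adjusted p = 0.714 with an estimated correlation). Aldoc, an aldolase (log2 1.55, SE 0.05, 1.83e-09), and Egln3, an oxygen sensor (log2 1.21, SE 0.10, 9.14e-07), were higher in all 3 KO libraries. Cholesterol synthesis genes rose in 19 of 25 cases and 1, the sterol enzyme Hsd17b7, fell (median log2 0.44, adjusted p = 9.26e-05; adjusted p = 0.714 with an estimated correlation), and fatty acid synthesis genes in 11 of 19, with Acsl4, which activates fatty acids, and Me1, which supplies NADPH, falling (median log2 0.26, adjusted p = 0.00751; adjusted p = 0.714 with an estimated correlation). Both had the same counts adjusted over the list alone. Lss, a cyclase of sterol synthesis (log2 0.93, SE 0.07, 4.69e-07), and the desaturase Fads1 (log2 0.78, SE 0.05, 1.11e-07) were higher in all 3 KO libraries.

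Of the genes that act in translation, Eef2k, the kinase that inhibits elongation factor Eef2, rose 1.67 times in KO total RNA (log2 0.74, SE 0.04, adjusted p = 1.06e-07; all 3 KO libraries above all 3 WT). Eef2 itself was slightly lower (log2 -0.19, SE 0.04, adjusted p = 0.00191, all 3 KO libraries below all 3 WT), as was Myc (log2 -0.18, SE 0.04, 0.00308, also 3 of 3), and neither passed in the fit on all 18 libraries (adjusted p = 0.252 and 0.230). Ribosomal protein genes rose by small amounts, 44 of 78 and 0 falling, the same adjusted over the list alone (median log2 0.12, adjusted p = 0.0161; adjusted p = 0.714 with an estimated correlation). In the fit on all 18 libraries the list did not pass (adjusted p = 0.197), and ribosomal protein genes have near-identical pseudogenes, so their counts are uncertain. Ribosome biogenesis genes rose in 18 of 49 cases and 1 fell (adjusted p = 0.355), initiation factors in 5 of 38 with 7 falling (0.975), and elongation factors in 2 of 15 with 3 falling (0.757). Adjusted over the list alone, these counts were 18 and 1, 4 and 6, and 2 and 3. Median and mean differed in sign for initiation (0.02 and -0.00044) and elongation factors (-0.0016 and 0.03), as for the Atf4 targets (-0.03 and 0.10). Targets of the stress factor Atf4 split, 13 rising and 11 falling of 40 (13 and 12 adjusted over the list alone, adjusted p = 0.559), and of BAF complex genes 4 of 24 rose and 10 fell, both ways of adjusting (median log2 -0.02, adjusted p = 0.559).

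Genes with large changes in total RNA led in the gradient fractions as well. H19 rose in polysomes (log2 4.62, SE 0.17, adjusted p = 2.77e-11) and in subpolysomes (log2 4.56, SE 0.15, 2.11e-16), Upk3b rose in both (log2 3.16, SE 0.15, and 3.29, SE 0.16), and Ctla2a fell in both (log2 -5.81, SE 0.29, and -5.91, SE 0.25). Eef2k rose in both (log2 0.81, SE 0.13, 0.000157, and log2 0.80, SE 0.13, 4.75e-05). In polysomes Ccr2, a chemokine receptor, rose (log2 2.92, SE 0.14, 3.85e-10) and Slco2a1 fell (log2 -5.52, SE 0.18, 6.21e-12). In subpolysomes Igf2 rose (log2 3.72, SE 0.15) and Csf2 (log2 -3.29, SE 0.16) and Fn1 (log2 -3.27, SE 0.15) fell. For each gene of this paragraph the 3 KO libraries of the fraction lay outside the range of the 3 WT libraries. In polysomes 1950 genes were higher and 1807 lower of 13066, and 2527 and 2503 with the replicate block, which those libraries call for. In subpolysomes 1391 were higher and 1391 lower of 12645. Groups did not overlap for 42.1% and 36.8% of genes, against 10% by chance.

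The changes of total RNA and of the fractions went together. Of 3524 genes that rose in total RNA and were tested in polysomes, 1831 rose there and 0 fell, and of 3417 that fell, 1683 fell and 0 rose. The polysome counts of this paragraph are from the fit without the replicate block. For subpolysomes, 1331 of 3434 rose and 1 fell, and 1304 of 3338 fell and 4 rose. Across 12895 genes the log2 fold changes in total RNA and in polysomes had a Pearson correlation of 0.940 and a rank correlation of 0.895, and those in total RNA and in subpolysomes 0.861 and 0.790. The same 11 gene lists passed in both fractions, each in its direction in total RNA. In polysomes, mitosis genes rose in 50 of 52 cases, DNA replication genes in 45 of 60 (48 adjusted over the list alone) and luminal genes in 17 of 28 with 1 falling (18 and 1 adjusted over the list alone), while EMT genes fell in 11 of 19. In subpolysomes the same lists gave 47 of 52 (49 adjusted over the list alone), 38 of 60 (39), 19 rising and 1 falling of 28, and 10 of 19 (11 with 1 rising, adjusted over the list alone). The other 7 were the squamous, interferon, NFkB cytokine, NRF2, glycolysis, cholesterol and Hippo lists. With an estimated correlation none passed, the adjusted p running from 0.387 to 0.921 in polysomes and from 0.0698 to 0.595 in subpolysomes. The Hippo list no longer passed in polysomes without KO 3 (adjusted p = 0.0709).

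**Figure D2:**
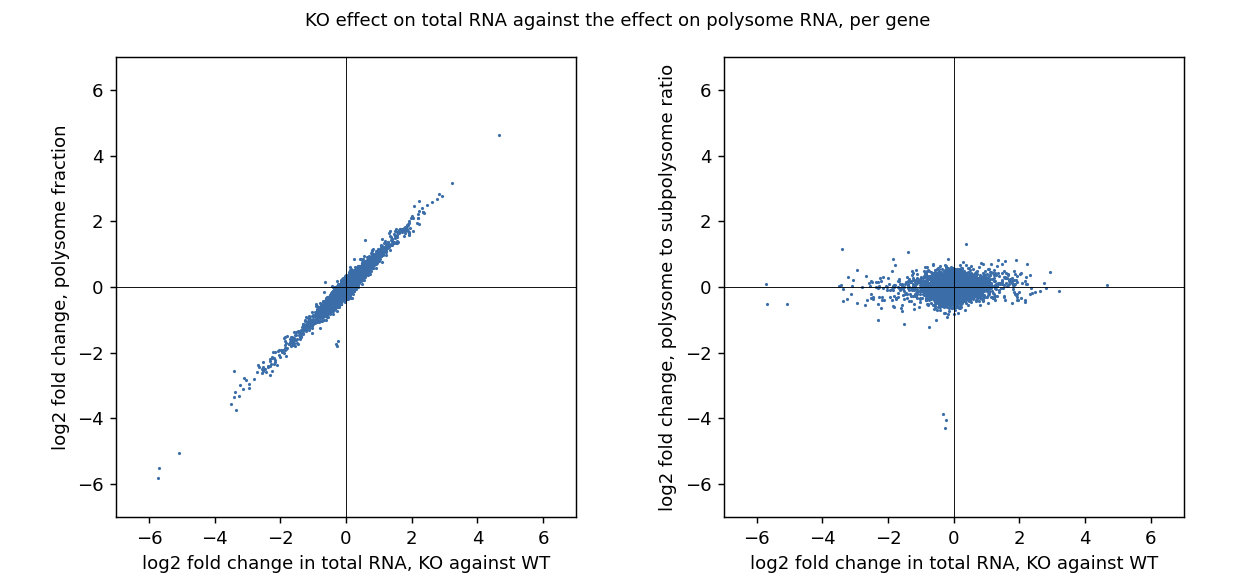
Each point is a gene with average log2 CPM of at least 4. The KO against WT log2 fold change in total RNA is set against that in polysomes (left; correlation 0.965 over the genes shown) and against that of the polysome to subpolysome ratio (right; 0.115 over the genes shown).

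The polysome to subpolysome ratio measures how far each mRNA sat on polysomes relative to the other mRNAs, so a change shared by all mRNAs would not show. In it 1 of 13392 genes differed between KO and WT in edgeR without the replicate block. This was C1s1, a complement protease gene on chromosome 6 (124530344 to 124542392, GRCm38), whose counts are uncertain because it has a close paralog, C1s2. It had 77, 114 and 117 counts in WT subpolysomes against 1, 0 and 1 in KO subpolysomes, and 435, 511 and 399 against 108, 132 and 89 in polysomes, so the ratio was higher in KO (log2 5.0, SE 0.72, adjusted p = 0.0119; 3 of 3 KO ratios above the WT ratios). In total RNA C1s1 had 387, 478 and 516 counts in WT and 67, 136 and 107 in KO. C1s1 did not pass without WT 2 (adjusted p = 0.0951), WT 3 (0.174), KO 1 (0.122) or KO 2 (0.258, with a log2 value of 4.25), which left 0 genes, and its fitted value rests on KO subpolysome counts of 0 and 1. At unadjusted p below 0.05 there were 758 genes, little above the share of 0.05 that chance alone would give. DESeq2 called 12 genes, the replicate block 12 (6 higher and 6 lower in KO) and the fit with no filter 29, C1s1 among them each time. Ratios did not overlap for 13.6% of genes, against 10% by chance. Eef2k (log2 0.02, SE 0.17, adjusted p = 0.994), Arid1a (log2 -0.66, SE 0.24, 0.877), Anxa1 (log2 -0.62, SE 0.18, 0.773), Cdkn1a (log2 -0.28, SE 0.16, 0.915) and Slc7a11 (log2 -0.25, SE 0.16, 0.920) did not pass. The sign of the Eef2k value turned without WT 2 (log2 -0.01), WT 3 (-0.01) or KO 2 (-0.04). Of 35 gene lists 0 passed, 5 had unadjusted p below 0.05, and the smallest adjusted p was 0.0805, for ribosomal proteins and p53 targets. With the replicate block 2 lists passed (1 higher and 1 lower in KO), with library size only 2, and without WT 2, KO 1 or KO 2 there were 1, 3 and 2. On simulated counts of this design 44.8% of genes changed 2 times and 78.8% of genes changed 4 times were called, so shifts of these sizes could be missed too.

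Among 3542 genes that rose in total RNA and were tested in the ratio, 0 rose and 0 fell in it, and among 3442 that fell 1 rose, C1s1. Across 13063 genes the log2 fold changes in total RNA and in the ratio had a Pearson correlation of -0.0188 and a rank correlation of 0.110. Over 8115 genes with average log2 CPM of at least 4 the values were 0.115 and 0.141, so the Pearson correlation changed sign. Set against total RNA in place of subpolysomes, polysome counts gave 0 genes of 13507 in edgeR, with 263 at unadjusted p below 0.05 and 0 by DESeq2, and ratios that did not overlap for 6.23% of genes against 10% by chance. The 263 genes are also fewer than the share of 0.05 that chance alone would give. This fit may thus be too strict, and its 0 is weak evidence of no change. In that comparison ribosomal protein mRNAs were shifted towards polysomes in KO as a list (median log2 0.10, adjusted p = 0.0356; adjusted p = 0.981 with an estimated correlation) and replication-dependent histone mRNAs away from them (median log2 -0.40, adjusted p = 0.0333; adjusted p = 0.981 with an estimated correlation), with 0 members passing in either, adjusted over the list alone or over all genes. The ribosomal shift had the opposite direction without WT 1 (adjusted p = 0.783) and without KO 3 (8.75e-06). It did not pass with size factors of the DESeq2 kind (0.0537), no filter (0.0645) or the replicate block (0.0585). The histone shift was lost without WT 1 (0.0539), WT 3 (0.928) or KO 2 (0.967), with those size factors (0.0537) and with no filter (0.623).

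**Figure D3:**
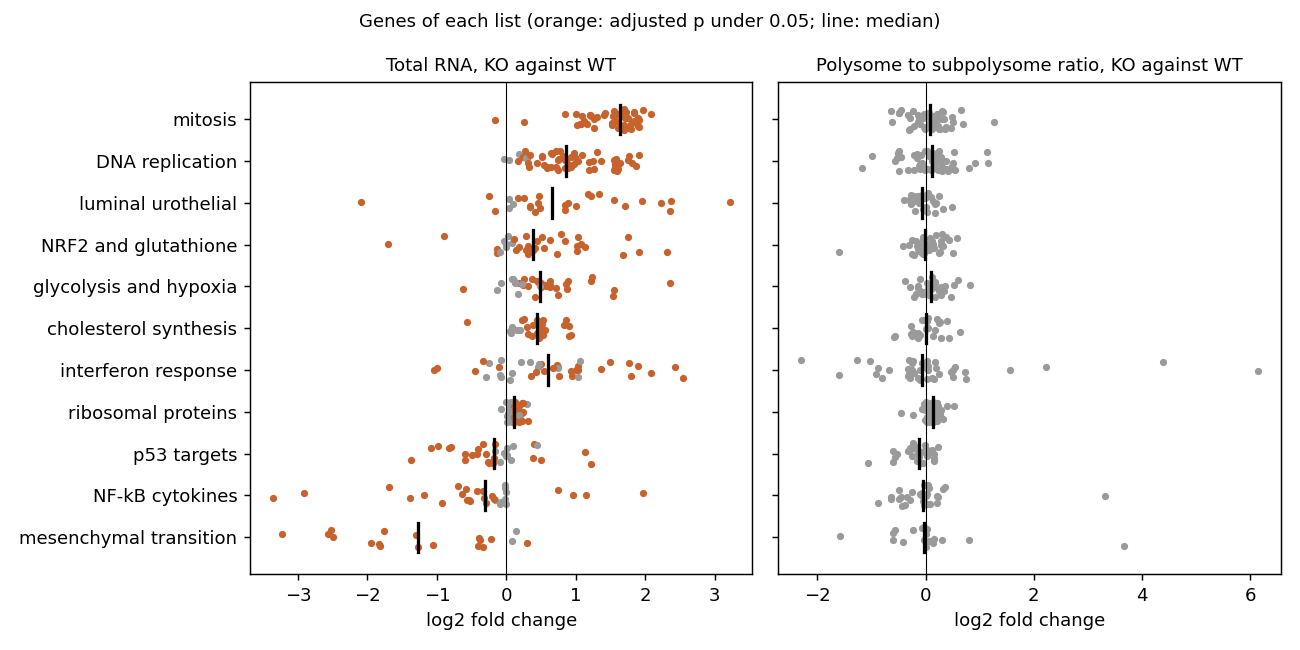
KO against WT log2 fold changes of the members of 11 gene lists in total RNA (left) and in the polysome to subpolysome ratio (right), with a line at each median and members of adjusted p below 0.05 in orange. Luminal genes had a median of 0.66 and EMT genes of -1.28 in total RNA. In the ratio 0 of the 35 lists tested passed without the replicate block, as drawn, and 2 passed with it.

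Genes differed strongly in how far their mRNA sat on polysomes relative to other mRNAs. In WT organoids Pcna, the sliding clamp of DNA replication (log2 2.95, SE 0.17, adjusted p = 3.69e-12), Prdx1, a peroxidase (log2 2.84, SE 0.16), Ccnd1, a cyclin (log2 1.54, SE 0.12), Eef2k (log2 1.31, SE 0.12, 1.06e-08) and Anxa1 (log2 1.09, SE 0.13) were higher in polysomes than in subpolysomes. Rpl41, a ribosomal protein (log2 -6.22, SE 0.21, 4.22e-15), Snhg6 and Gas5, host genes of small nucleolar RNAs (log2 -5.91, SE 0.15, 1.38e-16, and -5.66, SE 0.21), Eef2 (log2 -4.79, SE 0.20) and Atf4 (log2 -2.04, SE 0.14) were lower. For each of these genes the 3 polysome libraries lay outside the range of the 3 subpolysome libraries. KO organoids gave the same order of values, with Pcna at 3.06, Ccnd1 at 1.49, Eef2k at 1.33, Atf4 at -1.93, Eef2 at -4.51, Snhg6 at -6.00 and Rpl41 at -6.07 (log2, all past adjusted p of 0.05). In WT 4397 genes were higher and 4132 lower in polysomes of 13392, and in KO 4240 and 4005. Groups did not overlap for 68.7% and 64.8% of genes, against 10% by chance. The correlation of the WT and KO values across genes was 0.816 (rank correlation 0.881), both drawn from 1 fit on separate libraries.

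Relative to other mRNAs, nearly all ribosomal protein genes were on the subpolysome side. Of 79 members 78 were lower in polysomes and 1 higher in WT, and the same in KO, also when adjusted over the list alone. The median log2 was -3.60 in WT (adjusted p = 4.83e-89; adjusted p = 0.797 with an estimated correlation) and -3.52 in KO (1.27e-93; adjusted p = 0.743 with an estimated correlation). The member on the other side was Rpl34, named after its value was seen. Nuclear noncoding RNAs, a list made mostly of host genes of small nucleolar RNAs, which are spliced and exported, beside Malat1 and Neat1, which stay in the nucleus, were lower in polysomes in 15 of 16 cases in WT and 16 of 16 in KO, 0 being higher (median log2 -4.08 and -5.07, adjusted p = 3.55e-22 and 5.96e-25; adjusted p = 0.152 and 0.104 with an estimated correlation). Annexin mRNAs were on the polysome side, 9 of 12 in WT with 1 lower and 10 of 12 in KO (median log2 1.09 and 1.00, adjusted p = 0.00159 and 0.00189; adjusted p = 0.328 and 0.257 with an estimated correlation). Initiation factor mRNAs were mixed, 13 higher and 23 lower of 38 in WT, and 11 higher and 22 lower in KO (median log2 -0.52 and -0.49, adjusted p = 0.000282 and 0.000108; adjusted p = 0.936 and 0.831 with an estimated correlation). Adjusted over the list alone, the annexin count in WT was 10 higher and the initiation count in KO 12 higher and 23 lower. All these values are relative to the TMM scale. With library size only, all log2 values moved up by a median of 0.83 in WT and 0.89 in KO, more than the shift of the initiation list, and the share of called genes higher in polysomes went from 51.6% to 83.1% and from 51.4% to 85.9%.

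**Figure D4:**
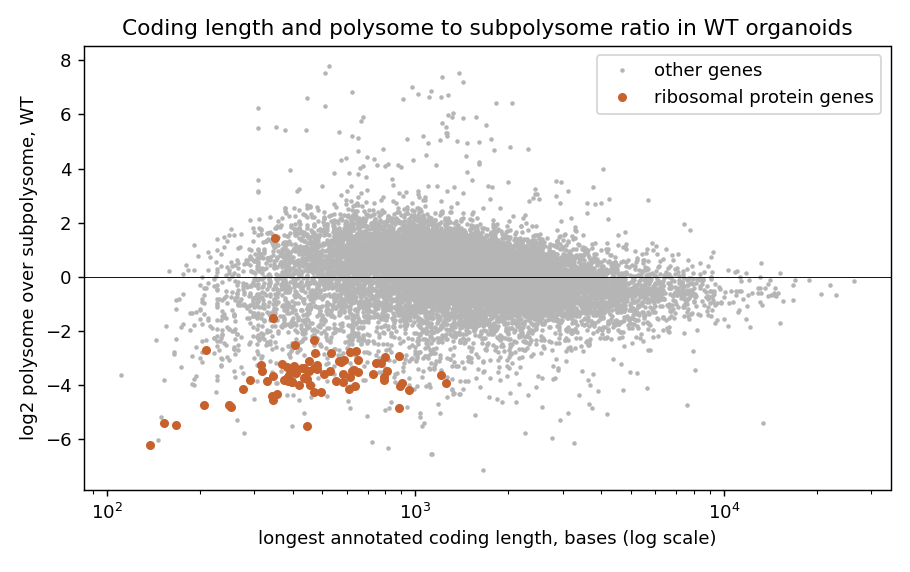
Longest annotated coding length of each gene against its WT log2 ratio of polysome to subpolysome counts, with ribosomal protein genes in orange. Their median ratio was -3.60 and their median coding length 456 bases, against 1377 for all genes shown, and the orange point above 0 is Rpl34.

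In the bladder cancer organoids, compared as labelled, Krt15, a basal keratin, went from 347 ± 3.95 CPM in the libraries labelled WT to 152 ± 18.6 in those labelled KO (n = 2 and 2; log2 -1.19, SE 0.15), and Ccl2, a chemokine, from 11.7 ± 1.98 to 55.4 ± 16.1 CPM (log2 2.24, SE 0.31). Both pairs of libraries lay apart for both genes, yet neither passed in edgeR (adjusted p = 1.00 for each), while DESeq2 called both (adjusted p = 1.69e-07 and 4.60e-06). In edgeR 0 of 12681 genes passed, and DESeq2 called 10. Unadjusted p was below 0.05 for 96 genes, fewer than the share of 0.05 that chance alone would give. On simulated counts of this design 16.7% of genes changed 4 times were called. Groups of libraries did not overlap for 20.6% of genes, against 33.3% by chance. Of the luminal genes, Upk3a was listed at 0 in all 4 libraries and Krt7 had means of 0.239 and 0.00926 CPM.

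As labelled, 16 lists passed in the cancer organoids, with 0 members passing over all genes. Adjusted over the list alone, 1 member passed, Krt15 of the basal list, which was lower against the direction of its list. Higher in the libraries labelled KO were basal urothelial genes (median log2 0.51, adjusted p = 0.000187), ligands of the EGF receptor (0.46, 0.00644), NFkB cytokines (0.31, 0.00644), annexins (0.20, 0.00700), immediate early genes (0.19, 0.00644) and, with medians of 0.06 to 0.13 and adjusted p of 0.00644 to 0.0352, ribosomal proteins, ribosome biogenesis, initiation factors, chaperones of the endoplasmic reticulum, oxidative phosphorylation and mitochondrial ribosome genes. Lower were interferon response genes (median log2 -0.40, adjusted p = 0.00307), histones (-0.32, 0.0231), antigen presentation (-0.24, 0.0367), luminal genes (-0.22, 0.000339) and DNA replication (-0.08, 0.0119). With an estimated correlation the adjusted p of these 16 ran from 0.682 to 0.828 and none passed. Without the library labelled WT 1, WT 2, KO 1 or KO 2, 13, 12, 8 and 7 lists passed, of which 8, 6, 6 and 5 were among these 16 (the 8 include 1 that turned in direction), and each of the 16 lost its call or turned in direction without at least 1 of them. The basal list did not pass without WT 1 (adjusted p = 0.151) or KO 2 (0.913), nor the luminal list without WT 2 (0.134) or KO 2 (0.787). Ligands of the EGF receptor did not pass without WT 2 (0.0584) or KO 2 (0.305), annexins without WT 1 (0.211) or KO 1 (0.609), and histones without WT 2 (0.956) or KO 2 (0.739). Immediate early genes did not pass without WT 2 (0.139), KO 1 (0.104) or KO 2 (0.0773), nor DNA replication without WT 2 (0.198), KO 1 (0.181) or KO 2 (0.0533). NFkB cytokines did not pass without WT 2 (0.929) and turned without KO 1 (0.609). Interferon genes turned without WT 1 (0.501) and did not pass without KO 2 (0.399). Antigen presentation turned without WT 1 (0.394) and KO 2 (0.980) and did not pass without KO 1 (0.0644). Oxidative phosphorylation turned without WT 1 (0.0484) and KO 1 (0.406), and ribosomal proteins did not pass without WT 1 (0.760) and turned without KO 1 (0.0673). Initiation factors did not pass without WT 1 (0.557), WT 2 (0.106), KO 1 (0.667) or KO 2 (0.0533), nor with the replicate block (0.0815). Ribosome biogenesis did not pass without WT 1 (0.606), WT 2 (0.0599) or KO 2 (0.854), chaperones without WT 2 (0.598), KO 1 (0.194) or KO 2 (0.0942), and the mitochondrial ribosome without WT 1 (0.559), WT 2 (0.0607) or KO 1 (0.667).

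The KO effect as labelled in the cancer organoids differed from that in the primary organoids for 448 of 14305 genes, 219 with the higher and 229 with the lower value in cancer. Slco2a1 (log2 difference 6.21, SE 0.99, adjusted p = 0.0235) and Ctla2a (6.01, SE 0.68, 0.00705) fell in the primary organoids, from 161 ± 17.4 to 3.14 ± 0.60 CPM and from 96.2 ± 18.1 to 1.82 ± 1.16 CPM. The value of Slco2a1 was 8.40 without the cancer library labelled WT 1 and 5.37 without the one labelled WT 2, and it did not pass without any 1 primary organoid library other than WT 1 (adjusted p from 0.0610 to 0.0803). The value of Ctla2a was 6.66 without KO 2 of the primary organoids. In the cancer organoids they had low values, 2.89 ± 3.20 and 4.23 ± 1.56 CPM, and 0.757 ± 0.0986 and 0.936 ± 0.0912 CPM. Aldh3a1, an aldehyde dehydrogenase, went from 215 ± 21.7 to 692 ± 71.4 CPM in the primary organoids and from 234 ± 36.9 to 55.7 ± 15.1 in cancer (-3.78, SE 0.27, adjusted p = 0.00135), with no overlap of libraries in either. Phospho1, a phosphatase of mineralizing matrix, went from 10.2 ± 1.09 to 47.7 ± 0.78 CPM and from 8.23 ± 1.99 to 5.71 ± 1.16 CPM (-2.78, SE 0.26, 0.00348). Mitosis genes differed as a list, 0 higher and 15 lower of 52 in cancer (median -1.64, adjusted p = 6.56e-36; adjusted p = 0.486 with an estimated correlation), as did DNA replication genes (0 and 20 of 60, median -0.94, 8.96e-32; adjusted p = 0.296 with an estimated correlation) and luminal genes (0 and 3 of 29, median -1.37, 9.79e-05; adjusted p = 0.296 with an estimated correlation). Adjusted over the list alone, 50, 50 and 4 members of these lists were lower. Lower here means a KO effect below that in the primary organoids, where these lists rose. Mitosis genes did not pass as a list in the cancer libraries alone. In all, 13 lists passed in this difference, 8 to 14 with 1 library left out and 0 with an estimated correlation.

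The fit of this difference took 1 spread per gene for both systems. The common coefficient of variation between libraries was 0.0677 in primary organoid total RNA, 0.508 in the cancer libraries and 0.296 in the joint fit. The joint fit thus understated the spread of the cancer libraries, and its 448 calls may be too many. The number of genes in this difference moved with the libraries used. Without a primary organoid library it was 283 (WT 1), 87 (WT 2), 72 (WT 3), 89 (KO 1), 156 (KO 2) and 74 (KO 3). Without a cancer library it was 750 (labelled WT 1), 2141 (WT 2), 2376 (KO 1) and 753 (KO 2). DESeq2 gave 1747 genes and the replicate block 201. Slco2a1 did not pass when any primary organoid library but WT 1 was left out (adjusted p from 0.0610 to 0.0803). No gene was called in both systems, since edgeR called 0 in cancer (96 at unadjusted p below 0.05), and 0 is the number for independent lists as well. With DESeq2 2 genes were called in the same direction and 5 in opposite directions. Across 11907 genes the KO effects in the 2 systems had a correlation of -0.0707 (rank correlation -0.0972).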

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

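The test of label exchange between cancer libraries by a signature score, the share of imprinted genes, the lists matched on coding length and the splits were fixed before their results were seen, while the tests of Arid1a spread between replicates, of mesenchymal genes and of separate animals or clones, the use of the replicate 2 cancer pair as a control, and the look at H19, Ddx3y and correlations of the cancer libraries were chosen only after the result was seen. The KO effect as labelled in the cancer organoids differed from that in the primary organoids for 448 genes, by a test of the difference itself. That test took 1 spread per gene for both systems and so understated the spread of the cancer libraries. The genes with the highest values were Dapk1 (log2 difference 8.84, SE 1.36, adjusted p = 0.0278), Col4a2 (7.49, SE 1.32, 0.0315), Serpine2 (7.25, SE 0.71, 0.00405), Slco2a1 (6.21, SE 0.99, 0.0235) and Ctla2a (6.01, SE 0.68, 0.00705), and those with the lowest were Krt7 (-4.14, SE 0.46, 0.00652), Aldh3a1 (-3.78, SE 0.27, 0.00135), Hopx (-3.20, SE 0.61, 0.0376), Krt19 (-3.04, SE 0.54, 0.0323) and Phospho1 (-2.78, SE 0.26, 0.00348). Dapk1 had 0 counts in both cancer libraries labelled WT, so its fitted value depends on the prior count, and Krt7 and Krt19 had under 2 CPM on average in the cancer libraries of either label. Leaving out any 1 primary organoid library ended the calls of Col4a2 (adjusted p from 0.0581 to 0.0986), Hopx (0.0749 to 0.115, and 0.0574 without the cancer library labelled KO 2) and Krt19 (0.0662 to 0.103), and leaving out any but WT 1 those of Dapk1 (0.0650 to 0.0851) and Slco2a1 (0.0610 to 0.0803). Several values depended on single cancer libraries. Without the one labelled WT 1 they were 11.99 for Serpine2, 9.35 for Col4a2, 8.40 for Slco2a1 and -2.24 for Hopx, and without WT 2 they were 6.27, 6.71 and 5.37 for the first 3. Without KO 1 they were 9.60 for Dapk1, 8.35 for Col4a2, -3.34 for Krt7, -3.82 for Hopx and -2.28 for Krt19, and without KO 2 they were 7.22 for Dapk1, 5.06 for Col4a2, -6.76 for Krt7 and -4.99 for Krt19. Ctla2a had 6.66 without KO 2 of the primary organoids, and Dapk1 had 7.97 in DESeq2. With the replicate block Col4a2 (adjusted p = 0.162), Krt7 (0.0543) and Krt19 (0.141) did not pass. In the polysome to subpolysome ratio C1s1 differed between genotypes (log2 5.0, SE 0.72, adjusted p = 0.0119), by the same kind of test. C1s1 did not pass without the culture WT 2 (adjusted p = 0.0951), WT 3 (0.174), KO 1 (0.122) or KO 2 (0.258). Its value rests on KO subpolysome counts of 1, 0 and 1.

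The Arid1a counts of the cancer libraries ran against the labels of replicate 1: the library labelled WT 2 had 2.87 times the CPM of the one labelled WT 1, and the one labelled KO 1 had 3.14 times that of the one labelled KO 2. With exchanged labels of the replicate 1 libraries as a candidate explanation, the mean signed level of genes called at least 2-fold in the primary organoids was higher in the library labelled WT 1 than in the one labelled KO 1 by 0.27 on the log2 scale, as an exchange predicts, but the same score did not part the replicate 2 libraries (KO 2 minus WT 2 of -0.04), so the test does not settle it. H19 was high in the libraries labelled WT 1 and KO 2 (18382 and 4088 counts, against 60 in WT 2 and 26 in KO 1). WT 2 and KO 1 had a centred correlation of 0.521 and WT 1 and KO 2 one of -0.0598, the highest among the pairs. All other pairs ran from -0.654 to -0.541. Centring so few libraries on their own mean pushes such correlations below 0, so only their order is read. These values go with an exchange but also with lines that differ. A spread of Arid1a reads between cancer lines with correct labels may also account for it, and the largest ratio between replicates in primary organoid total RNA, 1.14, bears on cultures of another kind and leaves this open. Ddx3y, with 12 counts in the library labelled KO 2 and 2578 to 3478 in the others, leaves open that this library came from another animal or line, which the sources used here do not give, so these explanations cannot be told apart and the cancer comparison may mix genotype with line.

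H19 and Igf2 were higher in KO organoids in every fraction. A larger share of mesenchymal cells, which express both in development, was tested by 5 fibroblast genes. Col1a1, Col1a2, Col3a1, Dcn and Lum together had 1.65 ± 0.19 CPM in KO and 3.32 ± 0.37 CPM in WT total RNA. H19 had 922 ± 104 CPM in KO. All are CPM of each library's own total without TMM factors. These values argue against more cells that express these 5 genes. Of 11 tested fibroblast and matrix genes 2 rose (Pdpn and Serpinf1) and 5 fell, so mesenchymal cells of other kinds are not excluded. For a general rise of imprinted genes, the rule set in advance asked that most of them rise. Of 31 other imprinted genes 13 rose (41.9%) and 9 fell, so this was not met. With a margin for 31 genes, which that rule did not state, the share could not be placed above or below it, and the question is not settled. Of all 13198 genes tested in total RNA, 3557 rose and 3468 fell. KO and WT cultures derived from different animals or clones could differ in this locus as well: the lowest KO library lay 4.12 above the highest WT library in log2 CPM of H19, which this source and genotype would give alike. An effect of Arid1a loss on the locus stays open and was not tested apart from these.

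Relative to other mRNAs, ribosomal protein mRNAs were lower in polysomes than in subpolysomes in both genotypes. The amount of RNA in each fraction was not measured, so the share of these mRNAs in either is not known. Short coding sequences, which hold fewer ribosomes, are excluded as the whole cause: the WT median of -3.60 lay outside 10000 lists matched on coding length, whose medians ran from -0.71 to 0.77. The matching used the 95.0% of tested genes with an annotated coding length. Regulation of this mRNA class, whose translation is known to follow growth signals, is a hypothesis that these data did not test, and where the gradient was divided is not given in the sources used here.

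For each comparison of 3 against 3 the 6 samples were split in every way into groups of equal size. The real split gave 7025 genes in total RNA, 3757 in polysomes, 2782 in subpolysomes, 1 in the polysome to subpolysome ratio, and 8529 and 8245 for polysomes against subpolysomes in WT and KO, and the highest of the other splits gave 0 in each. In each of these 1 of the 10 splits, the real one, gave as many genes. For polysomes against total RNA the real split gave 0, as did the other splits, 10 of 10. With 10 splits no share under 0.05 can be had. Every other split also put both genotypes, or both fractions, into each group. The differences between these widened the spread within groups, so few calls were to be had there. The 0 of those splits is therefore no support for the real split.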

How the results depend on the processing

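The fits without the genes of ribosomal RNA reads, with crossed pairing and with a minimum level in the ratio were chosen only after the result was seen, and the cause of the changes below was not tested. Among single genes the direction and side of the threshold were the same in 594 fits with 1 library or culture left out and 648 other fits, a call was lost in 37 and 7, gained in 2 and 5, and the direction turned in 3 and 1. Among single lists these numbers were 414 and 379 the same, 53 and 25 lost, and 9 and 0 turned. Gene and list counts were taken as kept within 1.5 times the value reported, and a relation if it differed from the value reported by no more than the SD of its values with a culture left out. By this bound gene counts and relations were kept in 43 and 51 fits and moved in 19 and 9, and list counts were kept in 46 and 40 and moved in 10 and 16.

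With the fit on all 18 libraries total RNA gave 3784 genes. The polysome to subpolysome ratio gave 29 genes with no filter, 12 with DESeq2, 12 with the replicate block and 0 to 1 with a culture left out. DESeq2 gave 10 genes in cancer and 1747 for the difference between systems. It called 2 genes in the same direction in both systems and 5 in opposite directions. The difference between systems gave 201 genes with the replicate block and 72 to 2376 with a library left out. The correlation of total RNA and ratio effects was 0.115 at average log2 CPM of at least 4 and -0.0515 to -0.0193 with a culture left out. With an estimated correlation 0 lists passed in every comparison, and what that run can find was not measured on simulated counts. The ratio gave 2 lists with library size only, 2 with the block and 0 to 3 with a culture left out. The polysome to total comparison gave 0 lists with size factors of the DESeq2 kind, 0 with no filter, 1 with the block and 1 to 6 with a culture left out. Polysomes against subpolysomes in KO gave 7 lists with library size only. Cancer gave 10 lists with library size only, 9 with no filter and 7 to 13 with a library left out, and the difference between systems 8 to 14.

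With a culture or library left out, directions turned as follows, with the range over all those left out. Eef2k in the ratio had log2 values from -0.043 (without KO 2) to 0.084 (without KO 1), turned also without WT 2 (-0.01) and WT 3 (-0.01), and had -0.0047 without the genes of ribosomal RNA reads. In the polysome to total comparison ribosomal proteins turned without WT 1 (adjusted p = 0.783) and KO 3 (8.75e-06), in a range of 1.16e-07 to 0.783. In cancer, without the library labelled WT 1, interferon (0.501; range 2.14e-07 to 0.501), antigen presentation (0.394; range 0.00618 to 0.980) and oxidative phosphorylation (0.0484; range 6.72e-07 to 0.406) turned. Without the one labelled KO 1, ribosomal proteins (0.0673; range 7.72e-13 to 0.760), NFkB cytokines (0.609; range 1.51e-11 to 0.929) and oxidative phosphorylation (0.406) turned, as did antigen presentation without the one labelled KO 2 (0.980).

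The replicate block, which the polysome libraries call for, changed no other single gene or list call printed for KO against WT in polysomes than that of Arid1a (counts of members in those lists were not run with it). Ribosomal proteins in the polysome to total comparison did not pass with it (adjusted p = 0.0585), and its effect on the ratio and on the difference between systems is given above. The rule used, that every same-numbered pair correlate above 0.1, did not call for the block in the other fits, where it gave 6937 genes in total RNA, 3239 in subpolysomes, and 8785 and 8512 for polysomes against subpolysomes in WT and KO. In subpolysomes each library correlated best with its own number, and in total RNA not every one did. Each polysome library correlated best with the subpolysome library of its own number, at 0.0549 to 0.155. The sample titles give both the same genotype and number, so this pairing is in the labels as well. The blocked fit of the ratio (12 genes and 2 lists) should therefore be read beside the unblocked one. In cancer the same-numbered libraries had a correlation of -0.429, and crossed pairing gave 0 genes and 11 lists, all 11 among the 16. Where leaving out a library left 1 in a cancer group, that library was assumed to vary like the others. Subpolysome libraries were the shallowest of the primary organoids, down to 39245248 counts, which limits the ratio for genes of few counts such as C1s1.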

Other observations

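The choice of imprinted genes, of genes of the Y chromosome, of H19 in the cancer libraries and of coding length as subjects of the tests below was made only after the result was seen for H19, for Arid1a in cancer or for ribosomal proteins. Beside H19 and Igf2, several imprinted genes differed between KO and WT total RNA. Ascl2, a transcription factor (log2 3.23, SE 0.76, adjusted p = 0.00382), Peg10 (2.45, SE 0.24, 5.16e-06), Peg3 (2.35, SE 0.47, 0.00125) and the cell cycle inhibitor Cdkn1c (2.17, SE 0.12, 5.67e-08) rose, while Cd81, a tetraspanin (-1.02, SE 0.06, 9.93e-08), and Phlda2 (-0.82, SE 0.11, 6.54e-05) fell. H19 had 18382 and 60 counts in the cancer libraries labelled WT and 26 and 4088 in those labelled KO. Centred on their mean, the cancer libraries labelled WT 2 and KO 1 had a correlation of 0.521 across genes, those labelled WT 1 and WT 2 of -0.635, and those labelled KO 1 and KO 2 of -0.654. Those labelled WT 1 and KO 2 had one of -0.0598. Centring so few libraries on their own mean pushes such correlations below 0.

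Xist, expressed from the inactive X chromosome, had 0 to 4 counts in the cancer libraries. The Y-linked gene Ddx3y had 3478 and 2578 counts in the cancer libraries labelled WT and 2896 in the one labelled KO 1, but 12 in the one labelled KO 2, where Kdm5d, Eif2s3y and Uty had 1, 4 and 3. In the primary organoids the Y-linked genes had log2 fold changes of -0.18 (Ddx3y), -0.02 (Eif2s3y), 0.13 (Kdm5d) and -0.23 (Uty).

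Coding length and the polysome to subpolysome ratio had a rank correlation of -0.202 in WT and -0.209 in KO across genes, and coding length and the KO effect on the ratio had one of -0.00570. The relation did not run one way: in 6 classes of rising coding length the WT median log2 ratio was -1.01 (the shortest, 245 genes), 0.23, 0.54, 0.36, -0.04 and -0.48 (the longest, 1701 genes). The ribosomal RNA precursor Rn45s took 5.59% of counts in the KO subpolysome library 3, the highest share of the 22 libraries.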
